A study of Homo sapiens with 4 samples.

How the data were processed

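The labels give 4 samples of the SH-SY5Y neuroblastoma line in collagen, 1 per group, with RNA extracted by TRIzol, libraries made with the Universal Plus mRNA-Seq NuQuant kit (TECAN) and paired-end sequencing on a NovaSeq X Plus. The series text speaks of biological triplicates and of 2 batches, while the labels list 1 sample per group and the same batch for all, so the labels were followed. The cell line field carries a running number from sample to sample, and the line is called SH-SY5Y here as in the descriptions. The deposited counts are exon fragments per gene, 1 column per library, whole numbers that per the file headers are raw, made by the authors on GRCh38 (hg38); the aligner, the counting tool and the annotation release are not given in the sources used here. The deposited FPKM values were computed by the authors from these fragments and the exon length with a single denominator per library. The means per group in the deposited table are FPKM averages by the authors, and the libraries that entered them are not named. The p-values were deposited by the authors per gene, per the file headers without adjustment, from a test that is not named in the sources used here. The signed fold changes were deposited by the authors as the ratio of the group means, or minus the inverse ratio below 1, with means of 0 replaced by 0.000001. The table holds 8 further columns of per-library values that no label maps to a sample, and these were not used in any step.

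The smallest ratio of a deposited group mean by the authors to the FPKM of the mapped library was 0.5 in each of the 4 groups, the value that an equal-weight mean with 1 further library at 0 would give. The number of genes at this smallest ratio was 252 for control, 283 for dcEF, 281 for red light and 289 for the combined group. The authors' deposited fold changes therefore share a library with the counts and add to them only through the rest of each mean. Adjusted values of the authors' p-values were computed here by the Benjamini-Hochberg method over the 15847 genes, and separately over each list alone.

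Gene identifiers are Ensembl identifiers, and 58552 of 58825 matched GENCODE release 29, 50986 of them with identical coordinates. GENCODE 29 transcripts gave the GC content, while gene types and the gene spans used for overlaps came from the deposited table. A suffix was removed from 1656 gene names in the file so that they could be matched to the lists.

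The gene filter, the scaling, the comparisons and the lists were fixed before the data were examined. A gene was kept with at least 10 fragments in at least 1 library, which left 15847. Scaling factors from the trimmed mean of M values (edgeR 4.0.16) were 0.909 for control, 1.02 for dcEF, 1.02 for red light and 1.06 for the combined library. Each log2 ratio added 0.5 to both counts, and its exact 95% interval came from the binomial distribution of 1 count given the sum of the 2. A gene was called higher or lower at 1.5-fold or more with an interval that excluded no difference. Departure from additivity was the combined against red light log2 ratio minus the dcEF against control log2 ratio, with an interval from the delta method. A gene at 0 fragments in a library was given only a bound, with 3 fragments in place of 0.

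The 48 gene lists held 1154 different genes, of which 1151 were found in the file. Each list was summarised by the median log2 ratio of its measured members and by its percentile among 10000 random lists matched on 20 bins of expression. An interval for each list median, used to judge the alternatives, came from 200 resamplings of the counts. The intervals printed with the tests of technical explanations came instead from 2000 resamplings of the genes, which are not independent of each other, and cover no difference between libraries. Named genes were taken by rule: for each comparison the 12 genes above and the 12 below with the interval bound farthest from 0, for the departure from additivity 8 each way, and for each list up to 4 members with the bound farthest from 0, or with the most fragments where no member was apart. Some results under these rules are not reported here. Clone names and pseudogenes were left out of this ranking. A gene was treated as nested when at least 50% of its span, introns included, lay inside the spans of other genes on the same strand. A gene within an intron of another gene therefore also counts as nested.

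Genes with at least 10 fragments numbered 14352 in control, 15098 in dcEF, 14847 in red light and 15015 in the combined library. Mitochondrial transcripts made up 7.53%, 7.88%, 8.43% and 7.97% of the fragments in that order, ribosomal protein genes 10.6%, 8.17%, 7.54% and 7.96%, and the 10 most abundant genes 8.28%, 12.7%, 10.3% and 10.2%. The most abundant gene was MT-RNR2 in control, at 1.14%, and IGF2 in the treated libraries, at 2.82%, 1.66% and 1.48%.

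The procedure was tested on simulated data with the depths of the libraries compared and 200 changed genes among 15847. For dcEF against control with counting error alone, the intervals covered the true value for 95.9% of genes, 125 unchanged genes (0.799%) were called, and 38% of the genes changed 1.5-fold, 84% at 2-fold, 100% at 4-fold and 96% at 8-fold were recovered, where a change planted at the minimum itself falls below it in part of the draws at any depth. For the departure from additivity these values were 95.2%, 245 genes (1.57%), and 28%, 80%, 96% and 92%. With an assumed biological coefficient of variation of 0.1 for dcEF against control, coverage was 65.4%, 393 unchanged genes (2.51%) were called and 26%, 90%, 98% and 98% were recovered. For the departure from additivity under the same variation, coverage was 65.0%, 1154 unchanged genes (7.38%) were called and 24%, 82%, 94% and 94% were recovered. A planted list of 30 genes shifted 1.5-fold in dcEF against control reached percentile 100 with and without that variation, and the same genes without the shift 17.8 and 69.8.

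The alternatives set in advance were scaling by DESeq2 size factors (1.42.0), scaling by total counts, no filter on low counts, a filter of 50 fragments, a minimum difference of 2-fold, 2 fragments added in proportion to library size and the assumed variation of 0.1. After the data had been seen, a comparison of dcEF with red light, a regression on GC content and exon length and a version without nested genes were added. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, matplotlib 3.10.9 and R 4.3.3.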

Results

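Poly(A) RNA was sequenced from SH-SY5Y cells, a human neuroblastoma line used as a model of sympathetic neuroblasts and neurons, embedded in a collagen gel of 1 mg/mL. The cells formed 4 groups: an untreated control, a direct current electric field (dcEF) of 175 mV/mm for 3 h, red light of 620 nm at 2 mW/cm² for 45 h, and the field together with the light. The labels map 1 library to each group, and all 4 libraries carry the same batch label. The library totals were 18560840 exon fragments for control, 17751782 for dcEF, 18140841 for red light and 18680432 for the combined treatment. A gene with no fragments could still be present at up to 3 fragments per library, which is 0.162 CPM in control, 0.169 in dcEF, 0.165 in red light and 0.161 in the combined library before TMM scaling. Of the 58825 annotated genes, 15847 had at least 10 fragments in at least 1 library and were compared.

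With 1 library per group there was no spread between replicates, so no test was run on the counts and no p-value is given for them. Each comparison sets 1 library against another and not 1 condition against another. Ratios are log2 ratios of counts scaled by the trimmed mean of M values (TMM), with exact Clopper-Pearson 95% intervals that cover counting error only. A gene counts as higher or lower where the ratio was at least 1.5-fold and its interval excluded no difference. The authors' deposited table adds mean FPKM per group, signed fold changes and p-values of a test that is not named, and its means include the libraries compared here, so the sources are not independent of each other. Its fold changes are on the FPKM scale, without TMM. Scaling by total counts in place of TMM moved the median ratio over all genes up by 0.16 in dcEF against control, by 0.17 in red light against control and by 0.22 in the combined treatment against control.

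The electric field alone was the first comparison, and the dcEF library stood out by its hypoxia genes. All 23 measured members of the hypoxia list, which holds genes switched on by the HIF transcription factors when oxygen is low, were higher than in control, with a median log2 ratio of 2.11 at percentile 100 among 10000 random lists matched on expression. BHLHE40, a transcriptional repressor that responds to hypoxia, was 57.0-fold higher, and CA12, a carbonic anhydrase of the cell surface, was 65.0-fold higher from 5 fragments in control. ADM, the vasodilator peptide adrenomedullin, was 8.94-fold higher and ANGPTL4, an inhibitor of lipoprotein lipase, 18.4-fold higher. In the authors' deposited table the median log2 fold change of the list was 1.37, and 10 members were higher with a p-value under 0.05, of which 7 passed when adjusted over the list alone and 1 when adjusted over all genes.

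The genes farthest above control in the dcEF library included a water channel, a calcium channel and a neuronal endopeptidase. AQP1, a water channel (ENSG00000240583, GRCh38 chromosome 7, 30911694 to 30925517), was at 12.1 CPM in control and 472 in dcEF, a log2 ratio of 5.29 (95% interval 5.09 to 5.50). CACNA1G, a T-type calcium channel (ENSG00000006283, chromosome 17, 50560715 to 50627474), was higher by a log2 ratio of 4.90 (4.34 to 5.60), and its signed fold change in the authors' deposited table was 17.1 with p 6.99e-06, or 0.0277 after adjustment over all genes. ECEL1, an endopeptidase of neurons known for its induction by nerve injury (ENSG00000171551, chromosome 2, 232479827 to 232487834), was 90.9-fold higher, with a log2 ratio of 6.51 (5.95 to 7.20). OLFML2A, a secreted olfactomedin protein, was 51.8-fold higher, NDUFA4L2, a mitochondrial protein induced by hypoxia, 42.9-fold, and ELFN1, a synaptic adhesion protein, 33.9-fold. CARTPT, a neuropeptide precursor, had no fragment in control and was at least 43.8-fold higher, and by the same bound STUM was at least 35.4-fold and WNT11 at least 28.6-fold higher. UTP14C was at least 24.9-fold higher, but its span lies inside that of ALG11 and its count is uncertain.

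The genes farthest below control included MYC, ADGRG1, LRRC4, LRRN3 and TXNIP. MYC, a driver of growth and ribosome production (ENSG00000136997, chromosome 8, 127735434 to 127742950), was 6.59-fold lower, with a signed fold change of -2.03 and p 0.156 in the authors' deposited table. ATOH8 was 13.8-fold lower from low counts, ADGRG1 was 9.31-fold lower, LRRC4 9.81-fold lower, TNNT2 7.09-fold lower and LRRN3 5.75-fold lower. TXNIP, an inhibitor of thioredoxin and of glucose uptake, was 5.63-fold lower. SCO2, HIST2H2AA4, BORCS7-ASMT and SULT1A4 also ranked here, but each shares sequence with or overlaps another gene, so their counts are uncertain.

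Among genes for neuronal structure and for neurotrophic signalling, more members were higher than lower in the dcEF library. In the neuronal cytoskeleton and growth cone list, 11 of 24 members were higher, 3 lower and 10 neither, with a median log2 ratio of 0.56. The neurofilament gene NEFL was 2.17-fold higher, the microtubule regulator STMN4 3.57-fold and the kinesin KIF5A 2.15-fold, while STMN3 was 2.02-fold lower. Among 23 neurotrophic factors and receptors, with a median of 0.34 that was 0.12 after regression on GC content and exon length, 8 were higher and 3 lower. NTRK2, the receptor for BDNF, was 22.8-fold higher from 5 fragments in control, and the neurotrophin receptor NGFR was 8.85-fold higher. VGF, a neuropeptide precursor induced by neurotrophins, was 4.63-fold higher, with a signed fold change of 3.91 and p 1.2e-05 in the authors' deposited table. IGF2, the most abundant gene of the dcEF library at 2.82% of its fragments, was 3.38-fold higher than in control. CREB targets had a median of 1.01, or 0.82 after that regression, with 10 of 17 members higher and 1 lower, among them the stress hormone gene CRH at 3.89-fold higher. Voltage-gated calcium channels had a median of 0.51, or 0.30 after that regression, with 3 of 12 members higher and none lower. Axon guidance genes had a median of -0.06, which turned to 0.11 with total-count scaling and was -0.21 after the regression, and 6 of 33 were higher and 5 lower. PLXNA4 was 4.60-fold lower and SEMA3A 4.51-fold higher. The synapse list had a median of 0.19, with 9 of 32 members higher and 2 lower, and the postsynaptic scaffold gene DLG4 was 2.84-fold higher.

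The matrix and mesenchymal lists had more than 0.5 of their members higher in the dcEF library. Marker lists of fibroblasts and of glial cells were on the same side, with medians of 0.74 and 0.97 over 9 members each. The glycolysis list had a median of 0.56, with 11 of 23 members higher and none lower, and the lactate transporter SLC16A3 was 6.52-fold higher, the hexokinase HK2 4.09-fold and the regulator PFKFB4 4.55-fold. In the mesenchymal neuroblastoma list, 12 of 20 members were higher and none lower, with a median of 0.78. VIM, the intermediate filament of mesenchymal cells, was 7.70-fold higher, ANXA2 7.74-fold, LGALS1 6.03-fold and S100A10 14.8-fold. The authors' deposited table gave a signed fold change of 7.65 with p 7.3e-05 for VIM and of 7.61 with p 5.6e-06 for ANXA2. Of 34 extracellular matrix genes, 19 were higher and 1 lower, with a median of 0.72, or 0.57 after regression on GC content and exon length, and the crosslinking enzyme LOXL2 was 10.1-fold and the collagen COL11A1 12.3-fold higher. Integrins and collagen receptors had a median of 0.59, or 0.29 after that regression, with 14 of 27 higher and 2 lower. The noradrenergic identity list went both ways, with 11 of 23 members higher, 5 lower and a median of 0.23. The vesicular transporter SLC18A2 was 8.57-fold and the growth regulator DLK1 4.40-fold higher, whereas HAND1 was 4.78-fold lower.

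Genes for DNA replication were lower in the dcEF library. In the S phase list, 34 of 35 members were lower and 1 neither, with a median log2 ratio of -1.55. The helicase subunits MCM2 and MCM5 were 4.87-fold and 4.22-fold lower, GINS2 was 4.70-fold lower and the flap endonuclease FEN1 4.36-fold lower. Values from the authors' deposited table were smaller, with a list median of -0.49 and no member with a p-value under 0.05. On the same FPKM scale this library pair had a median of -1.44, so the rest of the deposited means held less of the difference. Whether 1 library alone stands apart was not tested for this list. In the G2 and mitosis list, 19 of 35 members were lower and 16 neither, with a median of -0.60, and AURKB was 2.16-fold lower. Cytosolic ribosomal protein genes had a median of -0.57 at percentile 0.1, where random lists of like expression had a median of -0.37, with 35 of 78 members lower and 43 neither, and their share of all fragments was 8.17% against 10.6% in control. The heat shock list had a median of -0.50, with 10 of 24 members lower and 3 higher, and the chaperone HSPA8 was 2.71-fold lower. Transcripts of the mitochondrial genome had a median of -0.22, with 4 of 13 lower and none higher, but stood at percentile 76.7 because random lists of like expression had a median of -0.36. MT-CO3 was 1.95-fold lower. Notch pathway genes went both ways with a median of 0.63, or 0.13 after regression on GC content and exon length, the target HEY1 being 4.77-fold higher and the feedback gene NRARP 3.35-fold lower.

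**Figure D1:**
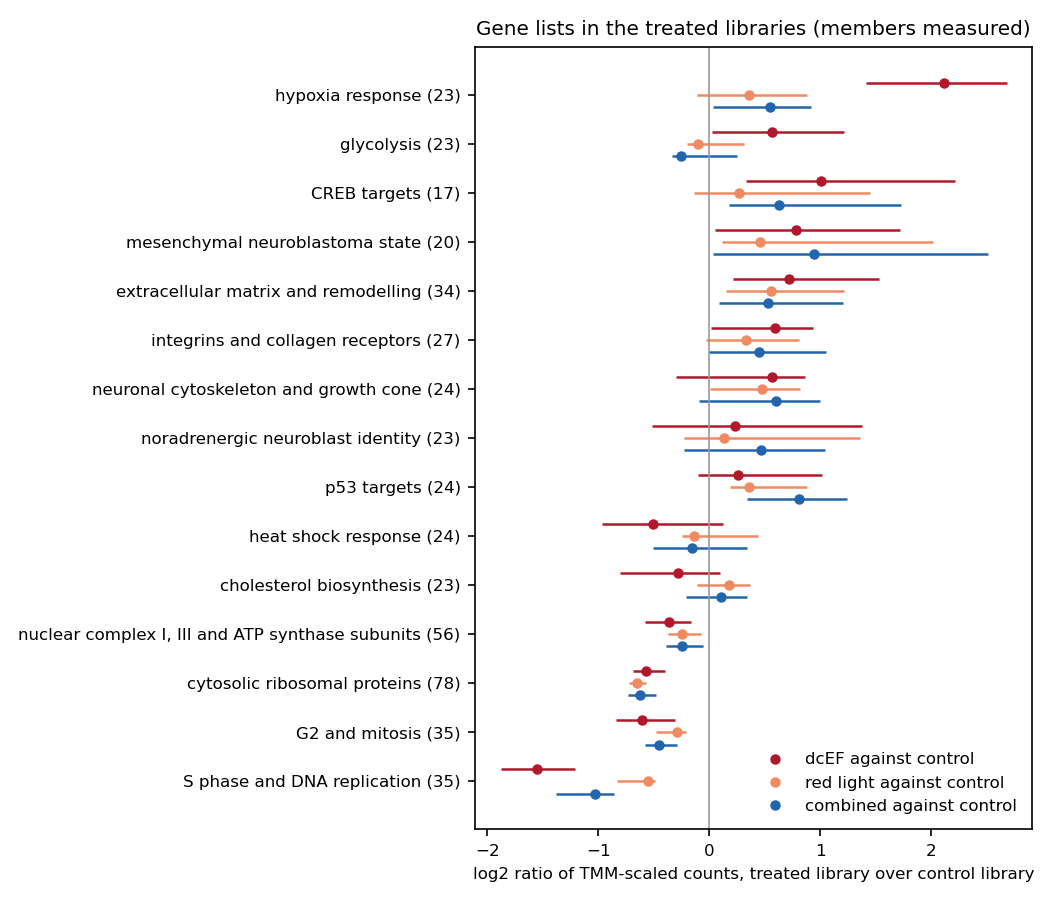
Median log2 ratio of TMM-scaled counts (dots) for 15 gene lists in the dcEF, red light and combined libraries against the control library, with lines from the lower to the upper quartile of the list members and the number of members in brackets. The hypoxia list had a median of 2.11 in dcEF, 0.36 in red light and 0.55 in the combined library, and the ribosomal protein list was negative in all 3, at -0.57, -0.65 and -0.62.

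In total, 6158 genes differed between the dcEF and control libraries, 3323 higher and 2835 lower, so that 54.0% were higher. With total-count scaling 6227 genes differed, 4305 higher and 1922 lower, or 69.1% higher. The authors' deposited table held 355 genes with a p-value under 0.05 in this comparison, 323 higher and 32 lower, or 2.24% of the genes compared. A well-calibrated test would give a share of 0.05 with no difference at all. Of the 355 genes, 10 passed when adjusted over all 15847 genes. Of the genes that differed between the libraries, 89.8% had the same direction in the authors' deposited fold changes. Since the same libraries entered the deposited means, this share was largely set in advance and gives no separate support.

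Red light alone was the second comparison, and the genes that differed most from control included PLXNA4 and NTRK3 on the lower side and NEUROG2 and SYT2 on the higher side. PLXNA4, a receptor for axon-repelling semaphorins (ENSG00000221866, chromosome 7, 132123332 to 132648688), was 13.1-fold lower, with a log2 ratio of -3.71 (-3.87 to -3.56), and had the smallest p-value of the comparison in the authors' deposited table, 4.72e-20, beside a signed fold change of -15.0. NTRK3, the receptor for neurotrophin-3 (ENSG00000140538, chromosome 15, 87859751 to 88256768), was 13.3-fold lower, with a signed fold change of -21.2 and p 1.1e-12 in the authors' deposited table. GFRA3, a receptor subunit for the neurotrophic factor artemin, was higher by a log2 ratio of 3.81 (3.12 to 4.68), and its signed fold change in the authors' deposited table was 34.9 with p 2.2e-15. NEUROG2, a transcription factor that starts neuronal differentiation, was 22.1-fold higher, and SYT2, a calcium sensor of synaptic vesicles, 35.0-fold higher from 7 fragments in control.

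Other genes at the top of this comparison included ECEL1, EDIL3, PHLDA1 and GDF15 on the higher side and SMAD6 and IGFBP3 on the lower side. ECEL1 was 131-fold higher than in control, at 182 CPM against 1.36, and EDIL3, a matrix protein that binds integrins, was 31.6-fold higher, with a signed fold change of 23.6 and p 1.26e-08 in the authors' deposited table. PHLDA1 had no fragment in control and was at least 39.2-fold higher, and the matrix link protein HAPLN1 was at least 20.1-fold, CARTPT at least 32.8-fold and the calcium channel subunit CACNA2D3 at least 13.7-fold higher by the same bound. CCDC80 had 2 fragments in control and 88 in red light, a log2 ratio of 5.01 with a wide interval of 3.43 to 8.39. GDF15, a stress-induced cytokine, was 20.8-fold higher and the zinc finger gene ZNF467 was 21.0-fold higher. AMIGO3 was at least 14.3-fold higher, but it lies inside GMPPB and its count is uncertain. On the lower side, ATOH8 was 14.1-fold, SMAD6, an inhibitor of BMP signalling, 8.47-fold, IGFBP3 10.3-fold, TNNT2 9.78-fold, ADAMTS17 7.15-fold and LRRN3 5.63-fold lower. PYY was lower with 2 fragments left in red light, a log2 ratio of -4.00 (-7.40 to -2.35).

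In most neuronal gene groups more members were higher than lower in the red light library, while fewer than 0.5 of each group were higher. In the neuronal cytoskeleton list, 11 of 24 members were higher, none lower and 13 neither, with a median log2 ratio of 0.48. DCX, a microtubule protein of migrating and immature neurons, was 3.32-fold higher, with a signed fold change of 3.03 and p 9.9e-05 in the authors' deposited table, and STMN4 was 5.48-fold, NEFL 2.37-fold and NEFM 2.22-fold higher. Neurotrophic factors and receptors had a median of 0.22, with 7 of 23 higher and 3 lower, among them NGFR at 11.3-fold higher. The noradrenergic list had a median of 0.13, with 10 of 23 higher and 3 lower. The granin CHGB, a protein of secretory vesicles, was 3.51-fold and SLC18A2 6.31-fold higher. Among axon guidance genes, with a median of 0.04, 8 of 33 were higher and 5 lower, the secreted SEMA3A being 4.16-fold higher and the receptor PLXNA2 2.36-fold lower. Calcium channels had a median of 0.42, with 3 of 12 higher and none lower. The synapse list had a median of 0.13, with 10 of 32 higher and 2 lower.

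In the mesenchymal, matrix and p53 lists more members were higher than lower under red light, though fewer than 0.5 of each list were higher. The mesenchymal list had a median of 0.46, with 8 of 20 members higher and 3 lower, beside medians of 0.78 for fibroblast and 0.88 for glial markers. ANXA2 was 8.21-fold, VIM 5.67-fold, S100A10 11.3-fold and the hyaluronan receptor CD44 15.1-fold higher. The matrix list had a median of 0.56, or 0.52 with genes at 0 fragments set to their bound, and 14 of 34 members were higher and 3 lower, with the metalloproteinase inhibitor TIMP3 5.00-fold higher. Integrins and collagen receptors had a median of 0.33, or 0.11 after regression on GC content and exon length, with 10 of 27 higher and 1 lower. Of the 24 p53 targets 10 were higher and none lower, with a median of 0.36. CDKN1A, which encodes the cell cycle inhibitor p21 (ENSG00000124762, chromosome 6, 36676460 to 36687339), was 4.68-fold higher, and the authors' deposited table gave a signed fold change of 5.88 with p 8.5e-10. The TGF-beta and BMP target list had a median of -0.37, with 5 of 13 lower and 3 higher. In the Notch list, 3 of 12 were higher and 3 lower, and LFNG, which modifies Notch, was 4.25-fold lower.

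Ribosomal protein genes were the most evenly lower group in red light. Their median was -0.65, where random lists of like expression had a median of -0.26, with 56 of 78 members lower and 22 neither, and RPLP0 was 1.92-fold lower. In the authors' deposited table the median of this list was -0.07. The S phase list had a median of -0.55, with 17 of 35 lower and 18 neither, and MCM2 was 2.15-fold and MCM3 2.09-fold lower. The G2 and mitosis list had a median of -0.29, with 5 of 35 lower. The hypoxia list had a median of 0.36, with 8 of 23 higher and 3 lower, BHLHE40 being 12.4-fold higher. For this list the authors' deposited table gave a median of 0.01, with 13 members above and 10 below no change. In the glycolysis list 1 of 23 members was higher and 1 lower, the median of -0.10 turning to 0.06 with total-count scaling, and the lactate transporter SLC16A1 was 2.42-fold lower. CREB targets had a median of 0.27, with 6 of 17 higher and 1 lower. The mitochondrial transcripts had a median of 0.05, which turned to -0.02 after regression on GC content and exon length, with none of 13 apart from control.

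**Figure D2:**
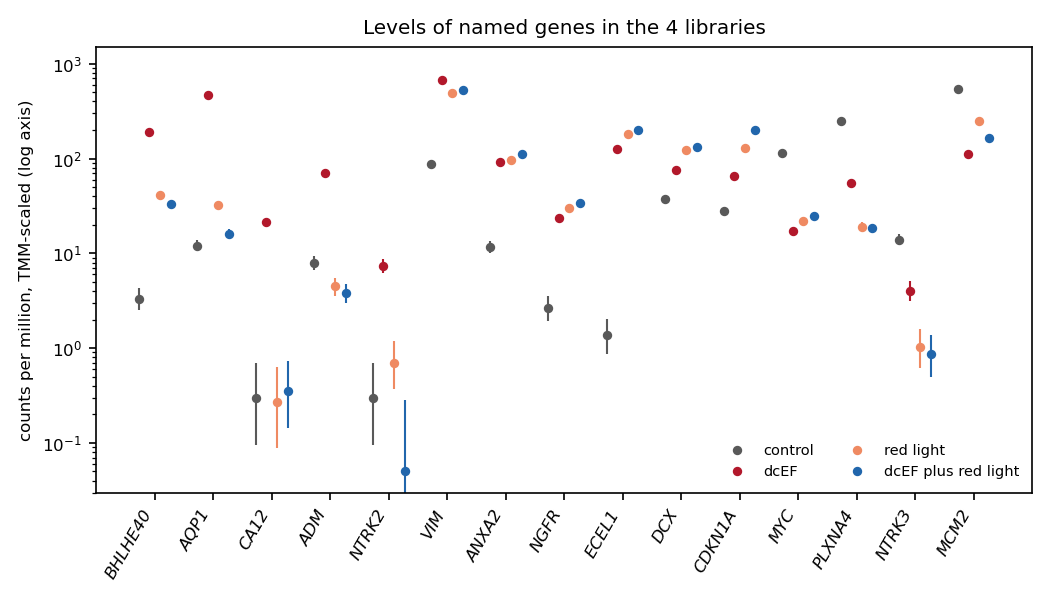
Expression as TMM-scaled CPM on a log axis for 15 named genes in the 4 libraries, with exact 95% Poisson intervals of the count. AQP1 stood at 472 CPM in dcEF and 16.1 in the combined library, against 12.1 in control.

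The red light and control libraries differed in 3571 genes, 1959 higher and 1612 lower. With total-count scaling the share that was higher went from 54.9% to 76.6%. The authors' deposited table held 522 genes with a p-value under 0.05, or 3.29% of the genes compared, 352 higher and 170 lower. Over all genes 35 passed, 22 higher and 13 lower. The direction in that deposited table of the authors was the same for 92.2% of the genes that differed, again with these libraries inside the deposited means.

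The combined treatment against control asked what field and light did together, and of the lists with no member lower, the p53 targets had the most members higher. Of the 24 p53 targets, 15 were higher and none lower, with a median of 0.81. CDKN1A was 7.21-fold higher, with a signed fold change of 7.50 and p 5.9e-12 in the authors' deposited table, SPATA18 was 5.93-fold and TP53INP1 3.40-fold higher. For this list the authors' deposited table held 10 members that were higher with a p-value under 0.05, and 5 passed when adjusted over the list alone and 1 over all genes. The neuronal cytoskeleton list had a median of 0.60, with 12 of 24 higher, 1 lower and 11 neither. DCX was 3.52-fold higher, with a signed fold change of 3.37 and p 1.8e-05 in the authors' deposited table, and GAP43, a protein of growing axons, was 2.35-fold higher.

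The genes farthest from control were largely those of the red light library. ECEL1 was 144-fold higher, with a log2 ratio of 7.17 (6.61 to 7.86), and its signed fold change in the authors' deposited table was 129 with p 2.19e-06. ZNF467 was 33.2-fold, SYT2 41.3-fold, EDIL3 34.6-fold, NEUROG2 25.5-fold and GDF15 23.2-fold higher. PHLDA1 was at least 30.2-fold and CARTPT at least 15.7-fold higher, and CCDC80 had a log2 ratio of 5.28 (3.71 to 8.66) over its 2 fragments in control. PLXNA4 was 13.7-fold lower, with a signed fold change of -3.97 and p 0.00118 in the authors' deposited table, where it had been -15.0 under red light alone. NTRK3 was 15.8-fold, ADAMTS17 13.6-fold, TNNT2 11.8-fold, SMAD6 9.04-fold, IGFBP3 9.29-fold and the homeobox gene CUX2 7.56-fold lower. Some of the top genes, among them AMIGO3, TNFRSF6B and the read-through transcripts PRR5-ARHGAP8, ZFP91-CNTF and BORCS7-ASMT, lie inside other genes and are uncertain.

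Other groups kept the side they had in the single treatments in part. The glycolysis list had a median of -0.26, with 1 of 23 higher and 3 lower, where it had been 0.56 in dcEF, but a median of 0.23 in the authors' deposited table, with 16 members above and 7 below no change. Axon guidance genes had a median of 0.02, which turned to -0.03 after regression on GC content and exon length, with 9 of 33 higher and 6 lower. The mesenchymal list had a median of 0.94, with 11 of 20 higher and 3 lower, ANXA2 being 9.53-fold and CD44 19.3-fold higher. In the noradrenergic list, 10 of 23 were higher and 3 lower, with a median of 0.46, and CHGB was 4.88-fold higher. Neurotrophic factors and receptors had a median of 0.35, with 6 of 23 higher and 3 lower, NGFR being 12.6-fold and GFRA3 10.9-fold higher. The matrix list had a median of 0.53, or 0.49 with zero counts at their bound, with 14 of 34 higher and 2 lower, and TIMP3 was 7.67-fold higher. Integrins had a median of 0.45, calcium channels of 0.54 and the synapse list of 0.12. CREB targets had a median of 0.63, or 0.38 with zero counts at their bound and 0.36 after regression on GC content and exon length, and 7 of 17 were higher and 2 lower. The TGF-beta and BMP list had a median of -0.58, with 5 of 13 lower and 3 higher. In the hypoxia list, 10 of 23 were higher and 3 lower, with a median of 0.55, and BHLHE40 was 9.90-fold higher. The S phase list had a median of -1.03, with 32 of 35 lower, and MCM2 was 3.24-fold lower. The G2 and mitosis list had a median of -0.45, with 9 of 35 lower, and the authors' deposited table held 9 members that were lower with a p-value under 0.05, none of which passed over the list alone. Ribosomal protein genes had a median of -0.62, beside -0.33 for random lists of like expression, with 46 of 78 lower and 32 neither. The mitochondrial transcripts had a median of -0.10, with 3 of 13 lower, which turned to 0.12 with total-count scaling and was -0.32 after the regression.

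The combined and control libraries differed in 4734 genes, 2397 higher and 2337 lower, so that 50.6% were higher against 75.1% with total-count scaling. The authors' deposited table held 679 genes with a p-value under 0.05, or 4.28% of the genes compared, 349 higher and 330 lower. Of the 679 genes, 22 passed over all genes. Directions matched the authors' deposited fold changes for 92.5% of the genes that differed, again with these libraries inside the deposited means.

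The combined treatment against dcEF asked what the light added to the field, and the hypoxia and glycolysis genes were lower in the combined library. All 23 measured hypoxia genes were lower, with a median log2 ratio of -1.47 at percentile 0. CA12 was 55.8-fold lower, ADM 18.5-fold and ANGPTL4 6.48-fold. For this list the authors' deposited table gave a median of -1.06, with 6 members lower at a p-value under 0.05, 4 of them when adjusted over the list alone and none over all genes. In the glycolysis list, 15 of 23 members were lower and none higher, with a median of -0.67, and the glucose transporter SLC2A1 was 3.70-fold, HK2 3.49-fold and PDK1 2.77-fold lower. AQP1 was 29.4-fold lower, with a log2 ratio of -4.88 (-5.05 to -4.72), OLFML2A was 23.4-fold and ELFN1 14.4-fold lower. STC1, a hormone of calcium balance, was 35.4-fold lower with 3 fragments left, and EPO, the erythropoietin gene, 32.5-fold lower with 2 left, log2 ratios of -5.15 (-7.66 to -3.78) and -5.02 (-8.41 to -3.43).

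The neurotrophic list went both ways between the combined and dcEF libraries, with 2 of 23 members higher, 5 lower and a median of -0.00, or 0.16 after regression on GC content and exon length. NTRK2 had 134 fragments in dcEF and 1 in the combined library, a log2 ratio of -6.61 (-12.5 to -4.69), and the authors' deposited table gave a signed fold change of -75.1 with p 8.4e-05. GFRA3 was 3.88-fold higher, with a signed fold change of 9.40 and p 1.69e-05 in the authors' deposited table, and GFRA2 was 7.39-fold lower. The chemokine CXCL12 had no fragment in the combined library and was at least 15.6-fold lower, the calcium-binding gene CABP7 was 52.9-fold and the transcription factor MAFA 37.7-fold lower. The Notch target HES1 was 6.50-fold and the ligand DLL1 8.57-fold lower, in a list with 5 of 12 members lower, 2 higher and a median of -0.32. Of 24 p53 targets 11 were higher and none lower, with a median of 0.56, CDKN1A being 3.02-fold and BTG2 2.14-fold higher. S phase genes had a median of 0.47, with 9 of 35 higher and none lower, the cell cycle factor E2F1 being 1.81-fold higher. The authors' deposited table gave the S phase list a median of 0.04, with 22 members above and 13 below no change. XAGE1B was 7.56-fold and BTK 4.54-fold higher. Among the 12 genes ranked farthest above dcEF, 6 lie mostly inside other genes, and the histone pair HIST2H2AA4 and HIST2H2AA3 moved in opposite directions, which reads shared between the copies would also give.

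The combined and dcEF libraries differed in 1981 genes, 601 higher and 1380 lower. The authors' deposited table held 91 genes with a p-value under 0.05, or 0.574% of the genes compared, 29 higher and 62 lower. Of the 91 genes, 3 passed over all genes, all of them lower. Directions in the authors' deposited fold changes were the same for 97.7% of the genes that differed, again with these libraries inside the deposited means.

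The combined treatment against red light asked what the field added to the light, and in the library counts some S phase genes were lower and some p53 targets higher. S phase genes had a median of -0.42 at percentile 0, with 7 of 35 lower and 28 neither, while the authors' deposited table gave them a median of 0.02 with 18 above and 17 below no change. TK1 was 1.67-fold, GINS2 1.68-fold and MCM5 1.60-fold lower. Of the 24 p53 targets 6 were higher and none lower, with a median of 0.33, ZMAT3 being 1.60-fold, CDKN1A 1.54-fold and the DNA repair gene DDB2 1.54-fold higher. The mesenchymal list had a median of 0.22, with ACTA2 at 1.83-fold and TAGLN at 1.90-fold higher. DUSP4, a phosphatase that limits MAP kinase signalling, was 1.85-fold higher, and MALAT1 was 1.75-fold higher.

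No member of several neuronal, hypoxia and ribosomal lists was apart between these libraries. None of the 24 neuronal cytoskeleton genes, of the 23 noradrenergic genes, of the 32 synapse genes or of the 78 ribosomal protein genes was apart, with medians of 0.00, 0.05, 0.02 and 0.03. For the ribosomal list the authors' deposited table gave a median of -0.20, with 73 of 78 members lower. The hypoxia list had a median of 0.05 and none of its 23 members was apart. NTRK2 had 13 fragments under red light and 1 in the combined library, a log2 ratio of -3.26 (-9.20 to -1.06). WT1 was lower with 1 fragment left, a log2 ratio of -4.00 (-9.92 to -1.92), and the collagen COL17A1 was 5.71-fold lower. TBX4 was 4.34-fold higher, and VEGFD, which had no fragment under red light, was at least 3.75-fold higher. GDF1 was 11.1-fold lower and had the smallest p-value of the comparison in the authors' deposited table, 1.11e-09, but all of it lies inside CERS1. CBWD3, 5.77-fold lower with p 1.29e-06 in the authors' deposited table, and NPIPB13, 4.57-fold higher, have near-identical copies, and 7 of the 12 genes ranked farthest below lie inside other genes.

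The combined and red light libraries differed in 833 genes, 433 higher and 400 lower. With total-count scaling 62.6% were higher in place of 52.0%. The authors' deposited table held 39 genes with a p-value under 0.05, or 0.246% of the genes compared, 19 higher and 20 lower, and 4 passed over all genes.

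**Figure D3:**
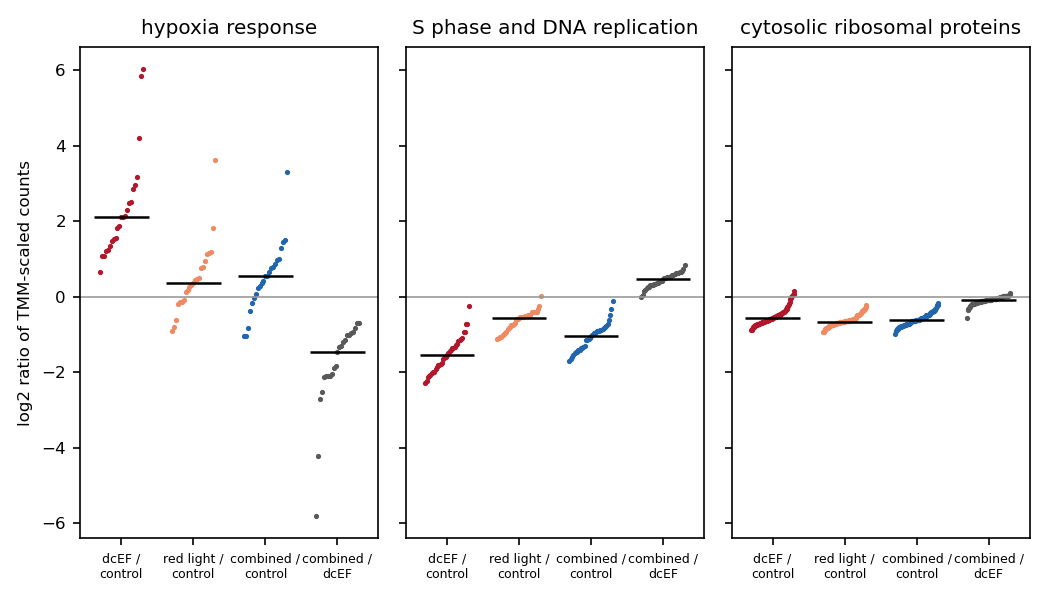
Log2 ratios of TMM-scaled counts of each measured member (dots) of the hypoxia, S phase and ribosomal protein lists in 4 comparisons, with the list median as a bar. All 23 hypoxia genes were above 0 in dcEF against control and below 0 in the combined treatment against dcEF, and the S phase medians were -1.55 in dcEF, -0.55 in red light and -1.03 in the combined library.

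The labels' design of field and light, alone and together, also asked whether the combined treatment equalled the sum of the single ones on the log2 scale. For the hypoxia genes the combined value fell below the sum in all 23 members, with a median of -1.89. AQP1 was below the sum by a log2 value of -6.31 (-6.59 to -6.02), BHLHE40 by -6.15 (-6.56 to -5.74), NDUFA4L2 by -5.78 and ELFN1 by -5.91. ECEL1, high in each treated library, was below the sum by -6.37 (-6.96 to -5.78). MYC, low in each treated library, was above the sum by 2.89 (2.64 to 3.15) and LRRN3 by 2.53 (2.31 to 2.76). A gene shifted alike in all 3 treated libraries departs from the sum by construction. An unusual control library alone would give the same departure. The mesenchymal gene VIM was below the sum by -2.86 and IGF2 by -1.98. S phase genes were above the sum in 32 of 35 members, with a median of 1.06, and ribosomal protein genes in 40 of 78, with a median of 0.59. The glycolysis list had a median of -0.62, the matrix list of -0.71, CREB targets of -0.94 and the neuronal cytoskeleton list of -0.41. In all, 2217 genes were above the sum and 2748 below it, so that 44.7% were above, against 32.6% with total-count scaling. These numbers include genes shifted alike in all treated libraries.

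Many genes stood on the same side of control in all 3 treated libraries. ECEL1, VIM, ANXA2, NGFR, DCX, GDF15 and CDKN1A were higher in each, and MYC, PLXNA4, NTRK3, SMAD6 and MCM2 lower in each, examples picked after their values were seen. Such genes numbered 1313 on the higher side and 1085 on the lower side, where independent lists of the same sizes would share 62.1 and 42.5. All of these comparisons use the same control library, which cannot be split into separate controls. In data simulated without any difference, 4 and 3 genes were shared with counting error alone, and 16 and 11 with an assumed biological coefficient of variation of 0.1. Across the 15847 genes, which are not independent replicates, the dcEF and red light ratios against control had a Pearson correlation of 0.745 and a Spearman correlation of 0.762, beside 0.517 in data simulated without any difference. Their covariance was 0.720, beside a simulated 0.0499 with counting error alone and 0.0716 with the assumed variation. Among well-covered genes the median absolute log2 difference was 0.363 between dcEF and control and 0.237 between red light and control, but 0.193 between dcEF and red light and 0.0989 between the combined and red light libraries.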

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

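The tests of whether 1 library alone stands apart and of a low level in the control library were chosen after the results were seen. The former were redone on the authors' FPKM scale after a first version had been seen. Predictions for the tests on GC content and on pseudogenes were written before their outcomes were seen. The regression on GC content and exon length was itself added after the data had been seen.

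Results were picked out here where a list median in the field comparison without light (dcEF against control) had the opposite sign in the field comparison with light (combined against red light) and the departure from additivity was at least 1.5-fold and outside nearly all random lists. The glycolysis list stood at 0.56 without light and -0.07 with light, and its members departed from additivity by a median of -0.618. For the cold-inducible RNA list these values were 0.85, -0.12 and -0.9705. Replication-dependent histones stood at -0.59 without light and 0.22 with light, a departure of 0.8097. Cytosolic ribosomal proteins stood at -0.57 and 0.03, a departure of 0.5899. With light, the counting intervals of the cold-inducible median (-0.229 to 0.029) and the histone median (-0.093 to 0.502) included no difference. The authors' deposited fold changes, on the FPKM scale, had no change of sign for glycolysis (0.58 without and 0.06 with light) and for ribosomal proteins (-0.47 and -0.20), and their medians without light were 0.07 for cold-inducible RNA and 0.02 for histones. After regression on GC content and exon length the ribosomal departure was 0.538 and the glycolysis departure -0.583, both under the 1.5-fold limit, and random lists of like expression had a median of 0.310 beside the ribosomal value. With total-count scaling the departure of the cytosolic ribosomal proteins was 0.476, also under the limit. A list lower by a like amount in every treated library, as the ribosomal list was, gets such a departure by construction. These differences between groups were not tested, since each group has 1 library.

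The first pattern is the 1313 genes higher and 1085 genes lower than control in all 3 treated libraries, which could come from an unusual control library as well as from a response that field and light share. If only this control library were unusual, and the other library in an equal-weight control mean of 2 sat at the treated level, the authors' deposited fold changes would be pulled toward 0. For 1240 of the higher genes the median deposited fold change was 1.01 against 0.53 expected under that explanation, an excess of 0.494 (0.457 to 0.537), which argues against it, also if more than 2 libraries entered the mean. For 1066 of the lower genes it was -0.34 against -0.46, a difference of -0.142 (-0.157 to -0.125) when counted in the direction of the change. The prediction asked for fold changes no larger than expected, and it was met. The fold changes also fell short of the expected value itself, so the test does not single this explanation out. For the lower genes it remains open. A difference in handling that touched every control library would pass these tests and is not excluded.

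The second pattern is the hypoxia genes, all 23 higher in the dcEF library. A low level in the control library does not account for it, since dcEF against red light, without the control, gave a median of 1.52 (1.22 to 2.01), and neither does a bias from GC content or length, with 1.87 (1.28 to 2.69) after regression. Whether this dcEF library alone stands apart stays open. On the FPKM scale this library pair had a median of 2.23, and the median authors' deposited fold change was 1.37. In an equal-weight mean of 2, a second dcEF library at the control level would give 1.51. The median difference per gene from that expectation was -0.0179 (-0.247 to 0.126), which includes no difference. The rest of the deposited mean therefore gave no sign of the rise, if 2 libraries entered it. The combined library, which received the same field, had a hypoxia median of 0.05 against red light with none of 23 members apart and of -1.47 against dcEF, which goes against an effect that this field brings in every culture. A fault or low oxygen in this dcEF culture, and an effect of the field that red light removes, are not separated here.

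The third pattern is the ribosomal protein genes, lower in all 3 treated libraries. GC content and length are unlikely to account for it, since the medians after regression were -0.466 (-0.529 to -0.413) in dcEF, -0.668 (-0.705 to -0.637) in red light and -0.606 (-0.671 to -0.569) in the combined library. Reads were not moved to the 45 annotated pseudogenes, which gained -0.656%, -0.786% and -0.715% of the CPM lost, that is, were lower too. An unusual control library stays open, since the same control serves all 3 comparisons. The authors' deposited fold changes lay beyond those expected under it by 0.221 (0.168 to 0.315) in dcEF and by 0.0530 (0.00349 to 0.0957) in the combined library. In red light they lay short of them, at -0.221 (-0.280 to -0.118). This met the prediction of no larger fold changes, but fell short of the expected value itself. Part of the pattern is shared by other abundant genes, as random lists of like expression had medians of -0.37, -0.26 and -0.33.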

How the results depend on the processing

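With the stricter minimum difference of 2-fold, which lowers each number by construction, the number of genes that differed was 3148 for dcEF against control, 1592 for red light against control, 2175 for the combined treatment against control, 973 for the combined treatment against dcEF and 467 against red light, and 2415 for the departure from additivity. At this minimum, dcEF against red light, a comparison added after the data were seen, had 1190 genes. A filter of at least 50 fragments, which tests fewer genes, left 435 genes in the combined treatment against red light, and the 6 other comparisons stayed within 1.5 times their number. DESeq2 size factors, total counts, no filter, 2 added fragments, the assumed coefficient of variation of 0.1 and leaving out nested genes, the last chosen after the data were seen, kept all 7 numbers within 1.5 times. Of the list medians over all comparisons, 27 moved out of their interval and 309 stayed with DESeq2 size factors. With total counts 147 moved and 189 stayed, and with the filter of 50 fragments 70 moved and 266 stayed. The GC content and length regression, which was also added later, moved 77 and left 259. Of the 1070 ratios of named genes, 45 moved with DESeq2 size factors and 293 with total counts, and none changed sides while apart. The correlation of the dcEF and red light ratios was 0.854 among genes with at least 500 fragments in the mean, against 0.745 over all genes, and the cause was not tested. No paired analysis was possible because each group has 1 library and the labels pair none; an additive fit of field and light leaves 1 residual degree of freedom, which is the departure from additivity itself, and was not used here. Since the labels map 1 library to each group, no leave-one-out run, no replicated edgeR or DESeq2 model and no model with a batch term was run. Depth leaves genes with fewer than 10 fragments in every library uncompared, and gives only a bound where a count was 0.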

Other observations

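In stress and signalling lists outside the comparisons above, members such as DDIT3, SPRY4 and SCN9A were higher than control in all 3 treated libraries. In the integrated stress response list, with medians of -0.01 in dcEF, 0.17 in red light and 0.06 in the combined library against control, 5, 9 and 7 of 28 members were higher, and the stress factor DDIT3 was 6.86-fold, 5.99-fold and 6.79-fold higher. In the authors' deposited table the integrated stress response list had medians of 0.39, 0.02 and 0.14. In dcEF 21 of its members were above and 7 below no change there. The heat-shock list outside dcEF had medians of -0.14 and -0.15. The unfolded protein list had medians of -0.09, 0.21 and -0.02, and EDEM1, which sends misfolded proteins to degradation, was 2.14-fold higher in red light. The authors' deposited table gave this list medians of 0.16, 0.10 and 0.20. The NRF2 list had medians of 0.26, 0.05 and 0.16, which were 0.08, 0.06 and 0.05 after regression on GC content and exon length, with NQO1, a quinone reductase, 2.63-fold higher in red light, and the general antioxidant list -0.19, -0.10 and -0.11, with the extracellular peroxidase GPX3 3.13-fold higher in red light. Apoptosis regulators had medians of -0.25, -0.16 and -0.07, and BID was 2.17-fold lower in dcEF. The immediate early list had medians of 0.21, -0.02 and 0.25 (0.19 with zero counts at their bound and 0.01 after regression on GC content and exon length), with 8 of 27 members higher and 8 lower in dcEF, and NR4A3 was 8.21-fold higher in red light. MAPK feedback genes had medians of 0.27, 0.34 and 0.23, with 7, 6 and 7 of 17 higher, and SPRY4 was 2.12-fold, 2.30-fold and 2.73-fold higher. Sodium and potassium channels had medians of 0.33, 0.34 and 0.36, which were 0.08, 0.10 and 0.24 after regression on GC content and exon length, and the sodium channel SCN9A was 3.54-fold, 3.98-fold and 4.59-fold higher. Light and heat sensing channels had medians of 0.84, 0.65 and 0.78, with the pressure-gated channel PIEZO1 9.59-fold higher in dcEF and the cation channel TRPM4 4.83-fold higher.

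In metabolic and chromatin lists, ATP5MC1, PPRC1 and HIST2H2AC were lower and COX4I2 and BHLHE41 higher in dcEF. Nuclear subunits of complexes I and III and of ATP synthase had medians of -0.36, -0.24 and -0.25, beside -0.23, -0.16 and -0.19 for random lists of like expression, with 14, 6 and 8 of 56 lower, while the authors' deposited table gave a median of 0.12 under red light with 37 above and 19 below no change, and ATP5MC1 was 2.34-fold lower in dcEF. Cytochrome c oxidase genes had medians of -0.22, -0.15 and -0.10, with COX4I2, a subunit isoform induced by hypoxia, 6.31-fold higher in dcEF. Regulators of mitochondrial biogenesis had medians of -0.27, -0.24 and -0.37, which were -0.44, -0.28 and -0.45 after regression on GC content and exon length. Of these 18 genes 8, 6 and 6 were lower and none higher, and PPRC1 was 3.13-fold lower in dcEF. Cholesterol synthesis genes had medians of -0.28, 0.18 and 0.10 (-0.46, 0.13 and 0.00 after that regression), and fatty acid synthesis genes -0.05, 0.20 and 0.10 (-0.19, 0.12 and 0.03 after it), with FASN 1.63-fold lower in dcEF. In the authors' deposited table the cholesterol list had medians of -0.10 in dcEF, 0.49 in red light and 0.47 in the combined group. Members above and below no change there were 6 and 17 in dcEF, 22 and 1 in red light, and 21 and 2 in the combined group. The clock list had medians of 0.36, -0.12 and 0.05, with BHLHE41 27.1-fold higher in dcEF and PER2 2.81-fold lower in red light. The cold-inducible list had medians of 0.85 (0.53 after that regression), 0.29 and 0.39, where CLK1 was 3.12-fold higher and RBM3 1.87-fold lower in dcEF. In the authors' deposited table the medians of the cold-inducible list were 0.07, -0.02 and -0.28. Replication-dependent histones had medians of -0.59, -0.27 and -0.15, and HIST2H2AC was 5.11-fold lower in dcEF; poly(A) selection captures such transcripts poorly. Metallothioneins had medians of -0.07, -0.32 and -0.24 (-0.37, -0.41 and -0.38 after that regression), with 2 of 6 lower in each. Nuclear retained RNAs had medians of 0.19, -0.20 and -0.18 (0.13, -0.33 and -0.27 after that regression), with MALAT1 5.53-fold and NEAT1 6.24-fold higher in dcEF. The authors' deposited table gave this list medians of -0.13, -0.30 and -0.31. YAP and serum response targets had medians of -0.04, 0.19 and 0.04, which were -0.14, 0.06 and -0.10 after that regression, and Wnt targets -0.38, -0.30 and -0.32. For the YAP list the authors' deposited table gave medians of 0.23, 0.25 and 0.20. NF-kB genes had medians of 0.11, -0.03 and -0.08, which were -0.008, -0.12 and -0.17 after that regression. Interferon genes had medians of 0.41, 0.06 and 0.45, or 0.21, 0.09 and 0.36 after it, where IRF9 was 7.48-fold, 7.15-fold and 7.72-fold higher. Notch genes had medians of -0.34 in red light and -0.14 in the combined library, and TGF-beta genes -0.05 in dcEF. Total-count scaling adds about 0.16, 0.17 and 0.22 to the medians in dcEF, red light and the combined library, so that the negative medians closer to 0 than this were positive with that scaling.

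Marker lists of other cell types were few in measured members, and their medians lay on the higher side in the treated libraries. Glial and Schwann precursor markers had medians of 0.97, 0.88 and 0.90 over 9 members, with MOXD1 6.53-fold higher in dcEF, and fibroblast markers 0.74, 0.78 and 0.62 over 9, with COL1A1 3.49-fold higher in dcEF. Epithelial markers had medians of 1.21, 0.02 and 0.35 over 8 members and blood and immune markers 0.88, 0.48 and 0.39 over 5, with the lysosomal protein gene CD68 9.82-fold higher in dcEF. In red light and in the combined library the counting intervals of the epithelial and blood medians included no difference. Between dcEF and red light, a comparison added after the data were seen, 1663 genes were higher and 988 lower in dcEF, and the hypoxia list had a median of 1.52.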
